A study of Homo sapiens with 6 samples.

How the data were processed

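Gene expression was measured by RNA sequencing in 6 libraries of the human hepatic stellate cell line LX-2, in 2 groups of 3. Groups were taken from the sample labels: cells with NSUN2 siRNA, and cells with NSUN2 siRNA followed by TGF-β1. The series' design text also names NAT10 for this siRNA, and the sample labels were followed. The comparison was TGF-β1 minus no TGF-β1.

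The deposited count table gives whole-number read counts per gene, not normalized, and the deposited FPKM table gives the authors' values per kilobase of gene length and scaled to library size. Per the submitters' processing notes, fastp and HISAT2 2.2.1 were used with genome build hg38; the counting tool, the use of strand and the annotation release are not given in the sources used here. All 58735 gene identifiers of the table, with their start, end and strand, were matched to GENCODE release 29, which was then used for exon positions and GC content. Within each library, the deposited FPKM values equalled counts divided by gene length and by a single library size, which was 1.07 to 1.08 times the total count in untreated libraries and 0.984 to 0.987 times in TGF-β1 libraries. FPKM therefore carries a scaling between libraries but no measurement independent of the counts. In each of the 2 tables, 6 further per-sample columns matched no sample of this series and were not used. Gene symbols are those of the table, which uses the older names CTGF for CCN2 and CYR61 for CCN1.

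Totals ran from 25828504 to 30034762 counts per library. Of 58735 genes, 33743 had at least 1 count and 17215 passed edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), 13444 of them protein-coding. Counts were tested with edgeR 4.0.16 (TMM factors, robust quasi-likelihood fit with glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment over the tested genes, adjusted p under 0.05), with the group as the only term and 4 residual degrees of freedom. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The common dispersion was 0.00316, a biological coefficient of variation of 5.62%. Normalised CPM values use TMM-scaled library sizes. The interval for FOXS1 is exact and conditional on the total count, and covers counting error only.

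Fixed were 31 gene lists, the rule for named genes and the alternatives, all before the data were examined. Lists with at least 3 tested members, 30 of the 31, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Calls within a list were counted from p-values adjusted over all tested genes and adjusted over the list alone. The genes named were NSUN2; the 8 higher and 8 lower genes with the largest change among called genes with a mean of at least 5 CPM, an established symbol and no overlap between groups; up to 3 called members of each list with the largest change and at least 5 CPM, or 2 abundant members where none was called; and ACTA2, COL1A1, COL1A2, COL3A1, FN1, CTGF, SMAD7, TIMP1, TGFB1, NAT10, ALYREF, YBX1 and MKI67 whatever their result. A further gene taken by this rule is not reported here. List members named because a count was 5 or fewer were chosen after their values were seen, as were 5 further lists (ERK feedback and EGFR ligands, Notch, desmosomes and keratins, WNT, guidance factors), which were adjusted among themselves.

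The scripts were tested on simulated counts with the real means, dispersions and library sizes over 17215 genes. In 10 draws with 200 changed genes each, the test recovered 47.4% of genes changed 1.25-fold, 62.2% of genes changed 1.5-fold, 76.6% of those changed 2-fold and 93.3% of those changed 4-fold. On average 8.02% of the calls were false, above the nominal 5%, and 4.91% of unchanged genes had an unadjusted p under 0.05. The number of draws was raised from 1 to 10 after the first draw had given a higher share of false calls. In a separate draw for the list test, over 16812 genes, a simulated rise of 1.5-fold in the ribosome biogenesis list was called, and 0 of 29 unchanged lists were. Each gene was drawn independently, so the simulated lists held no correlation between genes. This single draw therefore cannot show how often camera calls unchanged lists whose genes are correlated.

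Alternatives were DESeq2 size factors and upper-quartile factors in the edgeR test, no filter on low counts, at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, a fit that was not robust, limma-voom, the replicate number as a block, each library left out in turn, and limma on log2 FPKM with a pseudocount of 1 or 0.1 and a mean FPKM of at least 0.5, or with no filter. Scaling by library totals alone was added after the data were seen. Overlaps of exons were taken with bedtools 2.31.1, R was 4.3.3, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Without a stated use of strand, reads of genes that overlap on either strand cannot be told apart.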

Results

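RNA sequencing was carried out on 6 libraries of LX-2, an established human hepatic stellate cell line that is used as a model of the cells that lay down scar matrix in the liver. Per the sample labels, every library came from cells given a small interfering RNA (siRNA) against NSUN2, an RNA cytosine-5 methyltransferase. The series' design text calls the same siRNA both NAT10, after an RNA acetyltransferase, and NSUN2; the sample labels were followed, and the target cannot be settled from these libraries. In 3 libraries the cells had no further treatment, and in the other 3 they received TGF-β1, a cytokine that activates stellate cells, at 5 ng/ml for 24 hours beginning 48 hours after transfection. The labels call the replicates biological without saying whether they came from separate cultures or days, and the harvest time of the untreated cells is not labelled. The p-values therefore measure the spread between these libraries. Cells without NSUN2 siRNA were not analysed here, so the comparison describes the response to TGF-β1 in NSUN2 siRNA cells and does not address the effect of the siRNA.

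The untreated libraries held 30034762, 29257393 and 26957170 counts and the TGF-β1 libraries 25828504, 29978361 and 26921502. Log CPM values correlated at 0.988 to 0.990 within a group and at 0.971 to 0.974 between groups, and the first principal component, with 58.7% of the variance, separated the groups. The second, with 12.1%, spread the TGF-β1 libraries (scores of 33.1, -6.30 and -27.4 for replicates 1, 2 and 3) while the untreated ones lay between -1.60 and 1.67. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.83 to 5.22, so no library was a second deposit of another; this does not show that they came from separate cultures. The 10 most abundant genes took 4.34% to 4.41% of the counts in the untreated libraries and 5.92% to 6.06% in the TGF-β1 libraries. Transcripts of the mitochondrial genome took 2.28% to 2.36% and 2.00% to 2.12% of the counts.

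NSUN2, the siRNA target named in the sample labels (ENSG00000037474, chromosome 5, 6599239 to 6633291, minus strand, hg38), was measured in every library with 2364 to 2781 counts. Its normalised level was 82.9 ± 1.47 CPM in untreated cells and 100.6 ± 3.07 CPM with TGF-β1 (SD, n = 3), a log2 fold change of 0.28 ± 0.04 (SE). The rise passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 1.57e-06), and all 3 TGF-β1 libraries lay above all 3 untreated ones. The deposited FPKM values were 14.4, 14.6 and 14.9 in untreated cells and 18.1, 17.1 and 18.0 with TGF-β1. NSUN2 stood at percentiles 82.2 to 85.5 of the tested genes, and the extent of its knockdown could not be computed from these libraries.

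The comparison of TGF-β1 with no TGF-β1 asks which transcripts change when NSUN2 siRNA stellate cells are exposed to this fibrogenic cytokine. Fibronectin (FN1) rose 6.82-fold, the collagen chain gene COL1A1 2.82-fold and connective tissue growth factor (CTGF) 5.14-fold, and the interstitial collagenase MMP1 was 13.8-fold lower. Of 28 immediate TGF-β/SMAD targets 24 rose and 2 fell (adjusted p = 0.0905 with an estimated correlation), and of 28 ribosome biogenesis genes 25 rose and 0 fell (adjusted p = 0.0642 with an estimated correlation). Of 28 mitosis genes 18 fell by small amounts and 0 rose (adjusted p = 0.0975 with an estimated correlation). ACTA2, which encodes alpha smooth muscle actin and is a standard marker of activated stellate cells, was measured at a low level and fell by 0.74 ± 0.16 on the log2 scale.

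Of 17215 tested genes, 3471 rose and 3226 fell with TGF-β1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of the called genes was 0.37, and 62.6% of them changed by less than 0.5. At an absolute log2 fold change of at least 1, 536 genes rose and 585 fell. The groups did not overlap for 47.4% of the tested genes, where chance gives 10%. Scaling by library totals alone, a setting chosen after seeing the data, moved the median log2 fold change of all genes by -0.12 and gave 2019 higher and 5354 lower genes, so that 27.4% of the calls were higher against 51.8% with TMM factors.

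**Figure D1:**
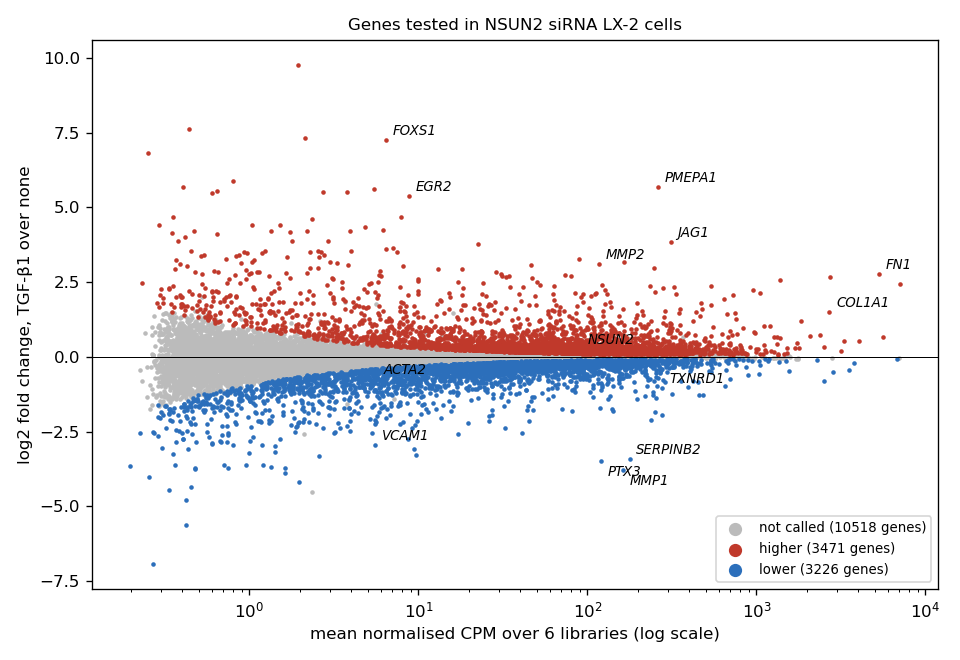
Log2 fold change of TGF-β1 over no TGF-β1 (vertical axis) against mean normalised CPM over the 6 libraries (horizontal axis, log scale) for the 17215 tested genes, with 3471 genes called higher in red, 3226 called lower in blue and the rest in grey. PMEPA1, at 5.70, and JAG1, at 3.83, stand out among well expressed genes that rose, and MMP1, at -3.79, among those that fell.

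Among genes with a mean of at least 5 CPM, the 8 largest rises included PMEPA1, a TGF-β-induced inhibitor of SMAD signalling (ENSG00000124225, chromosome 20, 57648392 to 57711536, minus strand), which went from 9.83 ± 0.84 to 512.0 ± 13.5 CPM (SD, n = 3; adjusted p = 1.80e-48). The Notch ligand JAG1 went from 40.7 ± 1.03 to 579.7 ± 28.6 CPM, a log2 fold change of 3.83 ± 0.04 (SE). The forkhead gene FOXS1 had 7 counts over the 3 untreated libraries and 1003 over the TGF-β1 libraries, a normalised ratio of 162.2 with an exact 95% interval of 78.4 to 404.5 that covers counting error only. ISLR2 rose by 5.63 ± 0.24 on the log2 scale, the zinc finger transcription factor EGR2 by 5.40 ± 0.19, the WNT ligand WNT7A by 4.67 ± 0.21, the hyaluronan-binding protein gene TNFAIP6 by 4.25 ± 0.21 and MYCT1 by 3.77 ± 0.21.

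The 8 largest decreases were led by MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160, minus strand), which went from 302.9 ± 5.66 to 21.9 ± 1.89 CPM (SD, n = 3; adjusted p = 2.33e-42). The pentraxin gene PTX3 and the protease inhibitor gene SERPINB2 had log2 fold changes of -3.50 ± 0.05 and -3.42 ± 0.05 (SE). PLEKHG4, a guanine nucleotide exchange factor gene, followed with -3.30 ± 0.17, then EVI2B with -3.07 ± 0.14 and the leukocyte adhesion molecule VCAM1 with -2.96 ± 0.19. The guidance factor SEMA3A had a value of -2.74 ± 0.16 and the tumour necrosis factor receptor TNFRSF1B one of -2.58 ± 0.11.

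**Figure D2:**
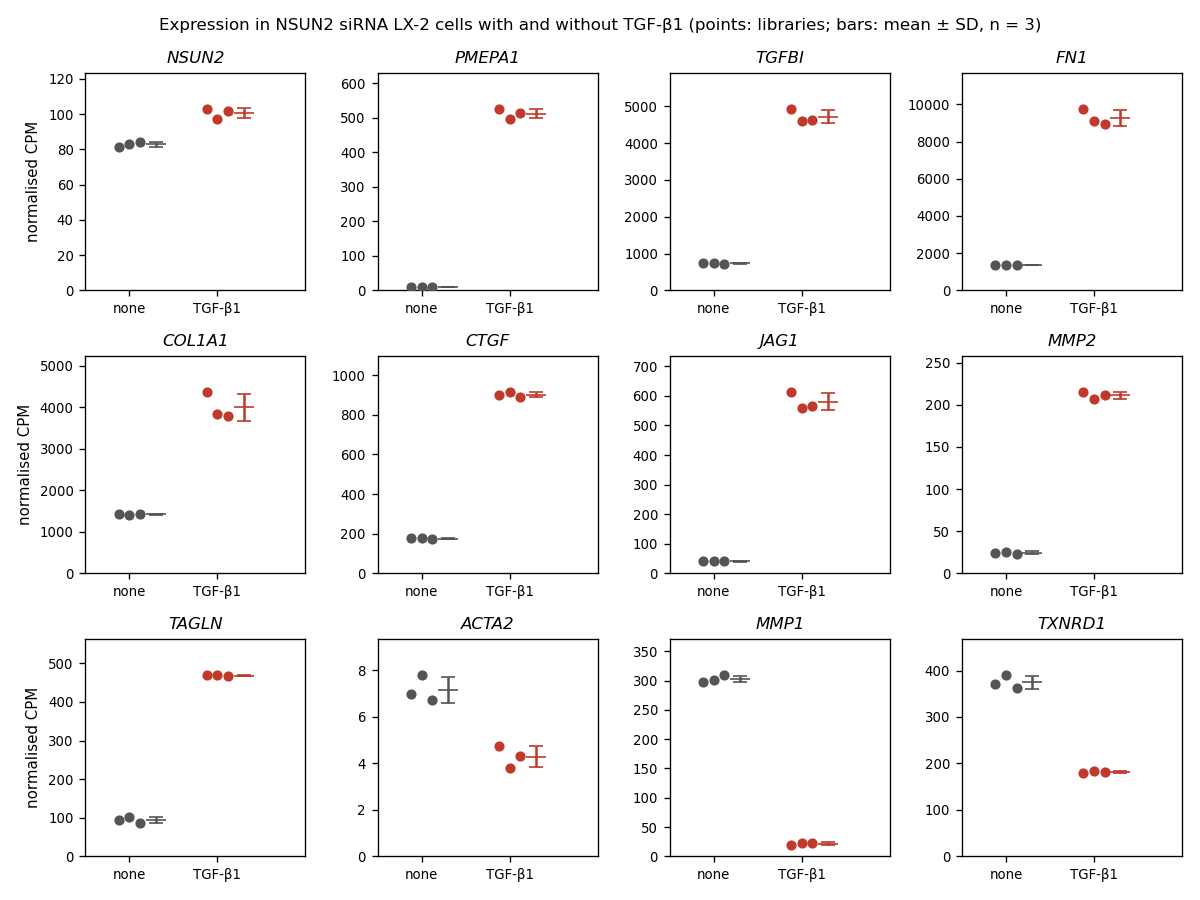
Normalised CPM (vertical axes, each starting at 0) of 12 genes in the 3 untreated libraries (grey) and the 3 TGF-β1 libraries (red) of NSUN2 siRNA cells, with points for libraries and bars for the mean and SD. The groups are separate for each gene shown, with FN1 at 1359 and 9265 CPM and ACTA2 at 7.15 and 4.29 CPM.

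The collagen list rose as a set, with 15 of 19 tested members higher and 2 lower (16 and 2 adjusted over the list alone) and a median log2 fold change of 0.93 (camera adjusted p = 2.98e-06; adjusted p = 0.277 with an estimated correlation). COL27A1 rose by 2.41, the basement membrane chain COL4A1 by 2.07, COL5A1 by 1.81, COL1A1 by 1.49 ± 0.05, COL1A2 by 1.28 ± 0.26 and COL3A1 by 0.91 ± 0.09. COL1A2 was expressed at only 1.30 and 3.18 CPM, against 1418 and 3993 CPM for COL1A1. TGF-β1 replicates 1 and 3 lay at opposite ends of the second component. Replicate 1 had the highest COL1A1 (4359 against 3844 and 3776 CPM) and COL5A1 (839.9 against 671.8 and 672.1 CPM). Without replicate 1 the list again gave 15 higher and 2 lower, with a median of 0.83 and log2 fold changes of 1.43 for COL1A1 and 1.70 for COL5A1. Without replicate 3 it gave 16 higher and 2 lower, with a median of 1.04 and log2 fold changes of 1.54 and 1.87. The collagens that fell were COL8A1 (-0.93) and COL12A1 (-0.81), which like other members named because a count was 5 or fewer were chosen after their values were seen. Among collagen processing and crosslinking enzymes, 14 of 22 rose and 1, CRTAP (-0.11), fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.71e-04; adjusted p = 0.0975 with an estimated correlation). The lysyl oxidase LOX rose by 1.18, the procollagen C-proteinase BMP1 by 0.99 and the lysyl hydroxylase PLOD2 by 0.81. With library totals alone this enzyme list gave 9 higher and 4 lower.

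Matrix glycoproteins and proteoglycans rose in 16 of 21 cases and fell in 4 (16 and 4 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 1.78e-06; adjusted p = 0.169 with an estimated correlation). FN1 rose from 1359 ± 12.9 to 9265 ± 420.8 CPM (SD, n = 3), LTBP2 by 2.75 and TGFBI by 2.69 on the log2 scale, while LAMA4 (-1.36), FBN2 (-0.30), EFEMP2 (-0.27) and LTBP1 (-0.25) fell. Matrix proteases and their inhibitors moved both ways, with 15 of 26 higher and 6 lower (15 and 6 adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.169 with an estimated correlation). The gelatinase MMP2 rose by 3.12 and the metalloproteinase inhibitor TIMP1 by 0.44, against the fall in MMP1.

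Immediate TGF-β/SMAD target genes had the highest median among the fixed lists, 1.75, with 24 of 28 members higher and 2 lower (24 and 3 adjusted over the list alone; camera adjusted p = 4.66e-15; adjusted p = 0.0905 with an estimated correlation). Beside PMEPA1 and LTBP2, LMCD1 rose by 2.72, the inhibitory SMAD gene SMAD7 by 2.40 ± 0.07 and CTGF by 2.36 ± 0.03. The members that fell, ID2 (-0.84) and ID1 (-0.30), encode inhibitors of basic helix-loop-helix factors, whereas ID3 of the same family rose by 0.48. TGF-β family ligands and receptors were mixed, with 10 of 23 higher and 7 lower (11 and 7 adjusted over the list alone), and the list test did not pass (camera adjusted p = 0.0717). In that list the ligand genes TGFB2, INHBA and TGFB1 rose by 2.72, 2.38 and 1.59, and the activin antagonist FSTL3 by 2.09. Lists share members, LTBP2 and TGFB2 among them, so their tests are not independent.

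Contractile and actin cytoskeleton genes rose in 19 of 26 cases and fell in 2 (19 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.10e-06; adjusted p = 0.169 with an estimated correlation). The smooth muscle gene TAGLN rose by 2.32, the tropomyosin gene TPM1 by 2.25 and the caldesmon gene CALD1 by 1.61. The members that fell were ACTA2 and the myosin light chain kinase gene MYLK (-0.55). ACTA2 (ENSG00000107796, chromosome 10, 88935074 to 88991339, minus strand) went from 7.15 ± 0.56 to 4.29 ± 0.46 CPM (SD, n = 3; adjusted p = 1.71e-04), with other annotated exons over 30.1% of its exonic bases. How the counting treated reads in such overlaps is not given in the sources used here, so a counting loss at ACTA2 is not excluded.

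Integrin and focal adhesion genes rose in 16 of 22 cases and fell in 2, ITGB8 (-1.82) and ITGA6 (-0.26) (16 and 2 adjusted over the list alone; camera adjusted p = 6.69e-07; adjusted p = 0.0642 with an estimated correlation). The cadherins CDH11 and CDH2, which that list also holds, rose by 3.19 and 1.21, and the integrin ITGAV by 1.40. Of 13 epithelial-mesenchymal transition transcription factors, 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0118; adjusted p = 0.169 with an estimated correlation). SOX4 rose by 2.49, SNAI1 by 2.48 and FOXC2 by 0.98, and TWIST1 (-0.60), SOX9 (-0.38), ZEB2 (-0.32) and RUNX2 (-0.31) fell.

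Markers of quiescent stellate cells fell in 8 of 16 cases and rose in 1, the intermediate filament gene VIM (0.08) (8 and 2 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0499; adjusted p = 0.169 with an estimated correlation). The transcription factor genes GATA4 (-0.77) and HAND2 (-0.74) and the neurotrophin receptor gene NGFR (-0.73) fell. That list call was lost without untreated replicate 2 (adjusted p = 0.108), without untreated replicate 3 (0.0513) and with library totals alone (0.0827), within a range of 0.00838 to 0.169 over the 10 alternative camera settings. Growth factor signalling genes of activated stellate cells rose in 10 of 24 cases and fell in 5 (11 and 6 adjusted over the list alone; camera adjusted p = 0.0283; adjusted p = 0.169 with an estimated correlation). PDGFB rose by 2.78, endothelin 1 (EDN1) by 2.34 and the receptor PDGFRB by 1.75, and IGFBP3 (-1.02), S100A6 (-0.95), AXL (-0.61), FGFR1 (-0.15) and LGALS1 (-0.13) fell, with 10 higher and 8 lower with library totals alone. YAP/TAZ targets rose in 12 of 22 cases and fell in 7 (12 and 7 adjusted over the list alone; camera adjusted p = 0.317), with ANKRD1 higher by 1.77.

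Inflammatory cytokines and NF-kB targets were divided, with 10 of 28 higher and 16 lower (10 and 16 adjusted over the list alone; camera adjusted p = 0.163). The cytokine IL6 rose by 2.72 and the chemokine CXCL12 by 2.08, while VCAM1 fell by 2.96. Interferon-stimulated genes fell in 8 of 28 cases and rose in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.106). BST2 (-0.45) and IFIT1 (-0.34) fell, and IFI44 (0.62) and OASL (0.18) rose; library totals alone gave 13 lower and 1 higher.

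DNA replication and G1/S genes fell in 16 of 28 cases and rose in 3 (17 and 4 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00382; adjusted p = 0.0975 with an estimated correlation). Library totals alone gave 22 lower and 2 higher, with a median of -0.33. E2F2 fell by 0.84. The members that rose were the growth regulators MYC (1.15) and CCND1 (0.58), which promote entry into the cell cycle, and the replication factor MCM10 (0.22). Mitosis and G2/M genes fell in 18 of 28 cases and rose in 0 (19 and 0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 2.12e-04; adjusted p = 0.0975 with an estimated correlation). TOP2A (-0.29), KIF20A (-0.26) and HMMR (-0.24) were among those that fell. The mitosis count was 22 lower with upper-quartile factors and 27 lower, with a median of -0.25, with library totals alone. The proliferation marker MKI67 changed by -0.07 ± 0.03 (adjusted p = 0.0363), a call that several other settings did not make. p53 targets fell in 9 of 22 cases and rose in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.199), with FAS (-0.56) lower and TP53I3 (1.24), PLK3 (0.56) and PHLDA3 (0.20) higher.

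Ribosome biogenesis genes rose in 25 of 28 cases and fell in 0 (25 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.31e-08; adjusted p = 0.0642 with an estimated correlation). Library totals alone gave 18 higher and 1 lower, with a median of 0.17. GAR1 rose by 0.64, the RNA helicase gene DDX21 by 0.62 and WDR43 by 0.55. Cholesterol synthesis and SREBP2 targets rose in 18 of 24 cases and fell in 1 (18 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 1.08e-05; adjusted p = 0.0642 with an estimated correlation). The synthase HMGCS1 and the sterol carrier STARD4 each rose by 1.00, and the sterol reductase gene TM7SF2 fell by 1.33; library totals alone gave 13 higher and 4 lower, with a median of 0.23. Fatty acid synthesis and lipid storage genes rose in 12 of 22 cases and fell in 7 (13 and 7 adjusted over the list alone; camera adjusted p = 0.0561). GPAM and ACLY, which act in lipid synthesis, rose by 1.75 and 0.75, and the triglyceride synthesis gene DGAT2 fell by 1.75.

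Glycolysis and glucose uptake genes rose in 4 of 22 cases and fell in 9 (5 and 9 adjusted over the list alone; camera adjusted p = 0.258). The members that rose were PFKFB3 (0.91), SLC2A1 (0.47), PFKP (0.15) and HK1 (0.12), and the glucose transporter SLC2A3 fell by 0.65; library totals alone gave 2 higher and 14 lower. NRF2 and oxidative stress genes rose in 7 of 26 cases and fell in 12 (7 and 12 adjusted over the list alone; camera adjusted p = 0.156). AKR1C1 (-1.60) and the thioredoxin reductase gene TXNRD1 (-1.05) fell, while the metallothionein MT1X rose by 0.98. ATF4 and unfolded protein response genes rose in 11 of 28 cases and fell in 7 (11 and 7 adjusted over the list alone; camera adjusted p = 0.346), and their median of 0.05 turned to -0.07, with 9 higher and 11 lower, with library totals alone. SLC7A11 fell by 1.23, and ALDH1L2 and XBP1 rose by 1.04 and 0.64.

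**Figure D3:**
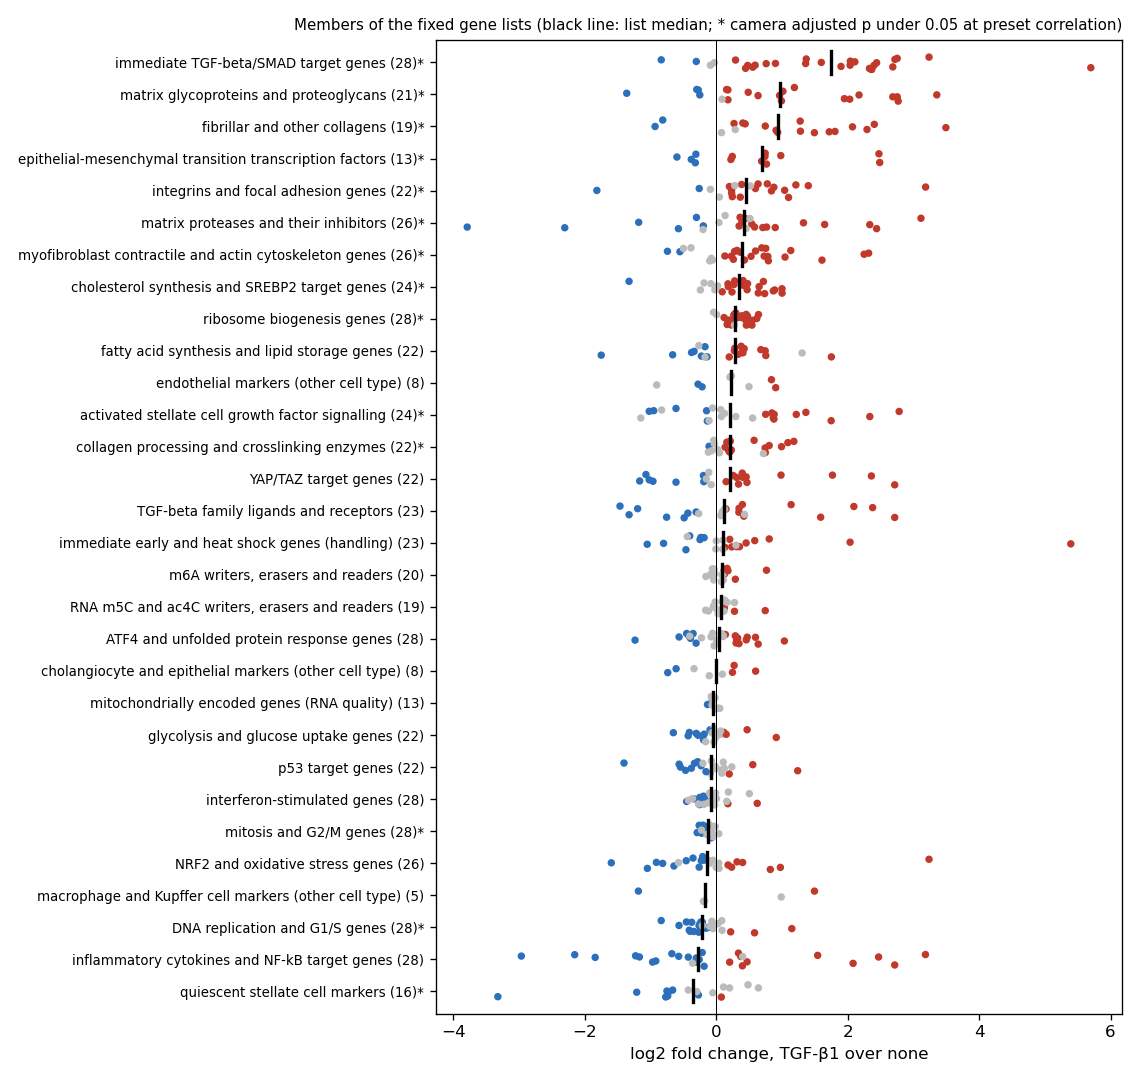
Log2 fold change (horizontal axis) of the tested members of 30 fixed gene lists, 1 row per list with the number tested in brackets, ordered by median; points are genes, red where called higher, blue where called lower and grey otherwise, and black lines are medians. The TGF-β/SMAD targets lie farthest to the right with a median of 1.75 and the quiescent stellate cell markers farthest to the left with -0.36; stars mark the 14 lists called at the preset correlation, none of which was called with an estimated one.

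RNA m5C and ac4C writers, erasers and readers rose in 4 of 19 cases and fell in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.199), and this balance held with DESeq2 size factors (4 and 0) but not under the other scalings: upper-quartile factors gave 2 higher and 2 lower, and library totals alone gave 2 higher and 4 lower, with the median turning from 0.08 to -0.04. Beside NSUN2 the members that rose were the demethylase TET3 (0.75), the m5C reader ALYREF (0.13, a call lost with upper-quartile factors and library totals) and SRSF2 (0.12). The acetyltransferase NAT10 had a log2 fold change of 0.03 ± 0.05 and the reader YBX1 one of -0.04 ± 0.03, neither past the test, although YBX1 was called lower with upper-quartile factors (-0.09) and library totals alone (-0.16). m6A writers, erasers and readers rose in 7 of 20 cases and fell in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.156), with IGF2BP1 higher by 0.76 and YTHDF1 by 0.29. The m6A balance likewise held with DESeq2 size factors (7 and 0) but not under the others: upper-quartile factors gave 2 higher and 1 lower, and library totals alone gave 2 higher and 7 lower, with the median turning from 0.09 to -0.03.

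Lists fixed to follow handling, RNA quality and other cell types gave the following. Immediate early and heat shock genes rose in 10 of 23 cases and fell in 7 (10 and 7 adjusted over the list alone; camera adjusted p = 0.197), with EGR2 and JUNB higher by 5.40 and 2.04 and FOS (-1.05) lower, and their median of 0.10 turned to -0.01 with library totals alone. Mitochondrially encoded genes fell in 2 of 13 cases, MT-CYB (-0.13) and MT-CO1 (-0.07), and rose in 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.288), but 7 fell with upper-quartile factors and 10 with library totals alone, where the median went from -0.05 to -0.17. Of the 20 hepatocyte markers 2 were expressed enough to test, and CPS1 rose by 0.20 (1 higher and 1 lower adjusted over the list alone). Macrophage markers gave 1 higher, CSF1R (4.34 and 12.3 CPM), and 1 lower, CD14 (-1.18), of 5 tested (2 and 1 adjusted over the list alone; camera adjusted p = 0.850), with a median of -0.18 against a mean of 0.19 and an upward list test. Endothelial markers gave 2 higher, FLT1 (0.91) and TEK (0.84), and 2 lower, EGFL7 (-0.28) and TIE1 (-0.21), of 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.732). Cholangiocyte and epithelial markers gave 3 higher, KRT7 (0.60), KRT8 (0.27) and KRT18 (0.25), and 2 lower, OCLN (-0.74) and SPP1 (-0.61), of 8 (3 and 2 adjusted over the list alone; camera adjusted p = 0.850).

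The list calls hold for camera at a preset correlation of 0.01 between genes: 11 lists were called higher and 3 lower. With an estimated correlation 0 were called, and the smallest adjusted p was 0.0642. The estimate lay below 0.01 for ribosome biogenesis (-0.011), cholesterol synthesis (-0.011) and integrin genes (0.004), among others. A higher correlation between genes thus cannot account for those lost calls. For other called lists the estimate was higher, up to 0.485 for the collagens. Reads of overlapping or near-identical genes cannot be assigned with certainty, which concerns EVI2B, TGFB2, TPM1, HAND2, NGFR, IL6, VIM, SRSF2 and ACTA2, with over 20% of their exonic bases under other genes, and AKR1C1 and MT1X, which have close relatives.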

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

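Scaling by library totals alone was chosen after the data were seen; the other settings were planned. Every gene called both in the main test and under another setting had the same direction in both, and no list call changed direction. The counts of higher genes stayed within 1.5 times the main value of 3471 in every setting but library totals alone (2019), and those of lower genes within 1.5 times 3226 except with library totals alone (5354) and limma on log2(FPKM + 1) without a filter (1978). Library totals alone differed from the main setting only in leaving out the TMM factors. Those factors were 1.041 to 1.043 in the untreated libraries and 0.957 to 0.963 in the TGF-β1 libraries. Which scaling is nearer to the true levels was not tested, nor was the cause of the lower count with log2(FPKM + 1) without a filter. Against 1121 genes called with an absolute log2 fold change of at least 1, limma on log2(FPKM + 1) gave a count of its own of 360, limma on log2(FPKM + 0.1) of 702 and limma on log2(FPKM + 1) without a filter of 349; adding a pseudocount shrinks the fold changes of low genes by construction. DESeq2's Wald test shared 6300 of the 6697 calls. Leaving out each library in turn gave 3089 to 3366 higher genes, 2850 to 3009 lower genes, 1058 to 1151 with the larger change, and 13 to 15 lists.

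Of the 14 lists called by camera, 0 were called with an estimated correlation, and fry, which asks another question, called 26 of 30. A higher correlation does not account for the first difference in the lists whose estimate lay below the preset value. The cause of that difference was otherwise not tested. The list of TGF-β family ligands and receptors passed with library totals alone (adjusted p = 0.0220), and fatty acid synthesis passed with library totals (0.0107) and without untreated replicate 2 (0.0493), TGF-β1 replicate 1 (0.0491) or TGF-β1 replicate 3 (0.0417). Over the 10 alternative camera settings their adjusted p ran from 0.0220 to 0.323 and from 0.0107 to 0.169. Among the 109 genes taken by the naming rule, MKI67, METTL3, ALYREF, MT-CO1, MT-CYB, CPS1, EGFL7, IGF2BP1 and COL1A2 lost their call in at least 1 setting, and YBX1 gained it in 2.

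The replicate numbers did not pair the samples: deviations of same-numbered libraries from their group means correlated at -0.00909 to 0.0111, and 2 of 6 libraries deviated most like their own number. With the replicate block, 3431 genes were higher, 3182 lower and 1108 past the larger change, 6542 of the calls were shared, and the same number of lists, 14, was called. At these totals, dispersions and group sizes, and with 200 of 17215 genes changed per draw, 62.2% of simulated 1.5-fold changes were recovered. In the real comparison 38.9% of the tested genes were called. The simulated recovery depends on the share of changed genes and so does not carry over to the real comparison. The part of depth alone was not tested.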

Other observations

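The 5 gene lists described first and the comparison of NSUN2 with ribosome biogenesis genes, and the spread and random lists for the medians corrected for GC content and length, were chosen after the results were seen; the other tests were written before theirs.

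Of 16 tested ligands, receptors and targets of the Notch pathway, 8 rose and 1, DLL4 (-0.92), fell (camera adjusted p = 0.0173; adjusted p = 0.307 with an estimated correlation), with the ligand JAG1 at 3.83, the receptor NOTCH3 at 1.16 and the target HES1 at 0.61. Desmosome and keratin genes, which epithelial cells use for cell contacts and filaments, rose in 9 of 13 cases and fell in 3 (camera adjusted p = 0.0173; adjusted p = 0.307 with an estimated correlation), with DSP at 2.99, KRT17 at 2.94 and KRT81 at 1.80, the keratin values being uncertain because of close relatives. In the desmosome and keratin list PKP2 (-0.89), PKP3 (-0.79) and KRT80 (-0.54) fell. Because these lists and those in the next paragraph were written after the results were seen, neither JAG1 nor their other members are independent evidence. The same holds for their list tests.

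Feedback genes of the ERK pathway and ligands of the EGF receptor fell in 14 of 23 cases and rose in 7 (camera adjusted p = 0.0316; adjusted p = 0.546 with an estimated correlation). The ligands AREG (-2.55) and EREG (-3.88 ± 0.50, SE) and the transcription factors ETV1 (-2.29) and FOSL1 (-1.38) fell. EREG was near the floor, at 3.05 CPM in untreated cells and 0.21 CPM with TGF-β1. MYC rose by 1.15 and the EGF receptor ligand HBEGF, at a higher level than EREG and AREG, by 0.75. The list of WNT ligands and antagonists, which also holds receptors and the transcription factor LEF1, was mixed, with 6 of 17 higher and 5 lower (camera adjusted p = 0.569). Among ligands WNT5B and WNT5A rose by 2.11 and 1.99 and WNT7B (-0.49) fell. Among antagonists SFRP1 (-1.95) and DKK1 (-1.75) fell and DACT1 and DKK3 rose by 3.05 and 0.25. The receptors FZD8 (-0.56) and FZD7 (-0.33) fell. Guidance genes likewise gave 12 higher and 11 lower of 27 (camera adjusted p = 0.960), with the receptors PLXNA2 and NRP2 higher by 1.55 and 1.48 and NRP1 (-0.86) lower, and the ligands SLIT2 (-1.02) lower and SEMA7A higher by 1.00.

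ACTA2 fell with TGF-β1 while most contractile genes rose. Too few reads is argued against, since ACTA2 stayed lower in all 6 fits that left out a library, with a highest adjusted p of 0.00241 and a highest log2 fold change of -0.66. Reads of overlapping genes may contribute: FAS and ACTA2-AS1 lie on the opposite strand over 30.1% of the ACTA2 exonic bases. Of the 2976 bases FAS shares 380 and ACTA2-AS1, which was not among the tested genes, shares 516. FAS fell by 0.56, a change that differs from that of ACTA2 by 0.18, close to the standard error of ACTA2 (0.16). An altered ACTA2 response in NSUN2 siRNA cells could also account for it. As 0 of the analysed libraries lack NSUN2 siRNA, that explanation was not tested and remains open. Without strand or reads, ACTA2 counts cannot be told apart from those of the overlapping genes, and reads dropped in the overlap were not tested.

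NSUN2 itself rose with TGF-β1 in cells transfected against it. Library scaling is argued against, since the lowest log2 fold change over 4 scalings was 0.16, with a standard error of 0.04. The rise was of the size found in ribosome biogenesis genes, 46.4% of which rose by less or fell. A similar size alone does not show a shared cause, so a rise shared with those genes remains open. The lists of m5C and ac4C genes (camera adjusted p = 0.199) and m6A genes (0.156) were not called. Waning of the siRNA could also raise NSUN2, if it coincided with the treatment, and 0 analysed libraries without NSUN2 siRNA leave this open.

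Of the 28 DNA replication genes 16 fell and 3, MYC and CCND1 among them, rose, and of the 28 mitosis genes 18 fell and 0 rose (adjusted p = 0.0975 with an estimated correlation for each list). Among 10000 random lists matched on expression, the medians of the mitosis and replication lists lay at percentiles of 0.01 and 0. Scaling moves listed and random genes alike, so it is argued against as the cause of the fall relative to matched genes. The comparison cannot show whether the medians lay below 0 free of scaling. Random lists do not keep the correlation among the genes of a list, so such percentiles may be too extreme. Removing the trend on GC content and gene length moved the medians from -0.13 to -0.0824 ± 0.0207 and from -0.21 to -0.160 ± 0.048 (SE from a bootstrap over list members). The same step removed the mean log2 fold change of all genes, -0.0186, so the trend made only a part of each shift. Over all genes the trend had an R2 of 0.00233. These values argue against that trend as the whole cause and leave a part open. The corrected medians lay at percentiles of 0.13 and 0.01 of matched random lists. A slower cell cycle after TGF-β1 is a hypothesis for this pattern that these data may support but do not test, because cell cycle phase was not measured. The harvest time of the untreated cells is also not labelled, so a difference in time since transfection cannot be told apart from TGF-β1.

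The 6 libraries can be split into 3 and 3 in 10 ways, of which the real grouping is 1, too few for a share under 0.05. The real split gave 3471 higher and 3226 lower genes, 1121 with the larger change and 14 lists; the highest among the other splits were 0, 0 and 0 genes and 7 lists. Every other split mixed treated with untreated libraries on each side and put unequal numbers of TGF-β1 libraries on its sides. Part of the TGF-β1 difference thus remained between the sides, and the mixing widened the spread within them. In these splits camera at its preset correlation called lists where edgeR called 0 genes. Because the treatment was not removed, they cannot show whether those list calls were false. Their counts of 0 genes are likewise no evidence for the real grouping.

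Genes whose exons are mostly covered by other annotated genes had low deposited values. Protein-coding genes with at least 50% of their exonic bases under other genes (587 genes) had a median of 0.121 FPKM, against 3.64 for 7268 genes with a smaller overlap and 2.95 for 8993 with none. ALDOA, a glycolytic enzyme gene with 53.5% of its exonic bases overlapped, stood at 5.94 CPM, and ILK, with 78.5%, at 2.12 CPM. Whether the counting dropped reads that fall in overlapping genes is not given in the sources used here, so these values are not taken as expression levels. ACTA2, with 30.1% overlap, belongs to the class with the smaller overlap. That class takes in every overlap above 0 and under 50%, so its median does not show whether genes with an overlap near that of ACTA2 lost reads.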
